A study of Rattus norvegicus with 9 samples.

How the data were processed

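Per the labels' protocols, pinealocytes were isolated from adult Sprague-Dawley rat pineal glands by papain digestion, cultured in medium with fetal bovine serum and transfected with Stealth siRNA at 40 nM using Lipofectamine RNAiMAX. The medium was changed after 24 h and cells were harvested on day 3. Total RNA had integrity numbers from 7.7 to 8.9, and 3.4 ng entered a stranded total RNA kit with ribosomal RNA depletion. The 9 barcoded libraries were pooled and sequenced on one HiSeq flow cell, 3 each with siNT, siLhx4 and siBsx. The labels call them triplicates without stating separate cultures or animals, so p-values of single genes measure the spread between these samples. Those of the list, family and marker tests compare genes with other genes.

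Per the submitters' processing notes, bcl2fastq 2.20.0.422, STAR 2.5.4a, featureCounts, Subread 1.5.2, DESeq2 1.16.1 and the rat genome build rn6 were used. The gene annotation, the strand setting and the handling of reads that match several genes were not given in the sources used here, so values of protocadherins and other gene families with similar copies are uncertain. Per the file legends, the authors deposited a table of all genes for each knockdown against siNT. The deposited signal values are the authors' mean normalized counts, that is, counts divided by a size factor per library and averaged over both groups. The deposited log2 values are the authors' log2 fold changes over siNT and, in the siBsx table, their standard errors. The score in the siBsx table is the authors' Wald statistic, which was checked to be the log2 fold change over its standard error. The deposited p-values are the authors' unadjusted p-values and those adjusted by the Benjamini-Hochberg method, listed for 14876 genes with a mean of at least 19.8 normalized counts in the siLhx4 table and 20.8 in the siBsx table. The authors also deposited normalized counts per library for 14 genes they chose in the siNT and siLhx4 libraries, with a standard error of the mean that was not used.

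Depth was read from those 14 genes. Their values were whole numbers of reads, at a tolerance of 1e-06 reads, after multiplication by size factors of 0.972, 1.26 and 1.22 for siNT replicates 1 to 3 and 1.46, 1.09 and 0.761 for siLhx4 replicates 1 to 3. The 14 genes had between 342743 and 724771 reads per library. Library totals were not used here. The precision of these genes is given as the SD between libraries.

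Group comparisons were fixed before the data were examined, as were the gene lists, the rule for named genes and most alternatives. Because the tables with all genes hold the authors' statistics without values per library, the genes past an adjusted p of 0.05 were counted from the authors' DESeq2 adjusted p-values, as planned for that case, and no model was refitted. Standard errors of the siLhx4 comparison were computed as the log2 fold change over the normal quantile of the deposited p-value. The deposited p-value of Lhx4 was listed at exactly 1e-200 beside an adjusted p of 0 and was not used for this, so its standard error was computed from the siBsx table's dispersion. Standard errors predicted in that way had a median ratio of 1.01 to those from p-values. The 14 genes were compared by two-sided exact permutation tests of mean log2 normalized counts with a pseudocount of 1.

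The siBsx and siLhx4 groups were compared by a Wald test rebuilt from both tables, with dispersions from the siBsx table. This test was added after the tables were seen, since the plan had no test for tables without values per library. The siNT means implied by both tables had ratios from 0.995 to 1.01 over 8459 genes, and the dispersions a median ratio of 1.02. On simulated data with 14876 genes, the rebuilt test recovered 84% of 100 genes with a log2 change of 1 and 70% of 100 genes with a change of 0.5, with 12 false calls. Of unchanged simulated genes, 5.38% had an unadjusted p under 0.05. The simulated test was given the dispersions that generated the counts. It therefore leaves out the error of estimating dispersions from few libraries and does not give the error rate on the real data.

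Gene lists of at least 5 tested members were tested with cameraPR of limma 3.58.1 in R 4.3.3, two-sided, on the Wald statistic, with the preset inter-gene correlation of 0.01 and adjustment over lists and comparisons. An estimated correlation needs values per library of all genes and was not run. In simulated data with independent genes, 48 of 50 draws called the changed list and 3 of 850 unchanged lists were called. These rates leave out correlation between the genes of a list and need not hold for the real lists. The lists covered melatonin synthesis, night-induced genes, adrenergic signalling, rod and cone phototransduction, transcription factors, the clock, synapses, interferon response, stress, cholesterol synthesis, the cell cycle, and markers of astrocytes, microglia, endothelium, fibroblasts, mural cells and Schwann cells. A list of mitochondrially encoded genes, and Otx2, Insm1, Prph2, Ccnb2, Pecam1 and Bbc3, were not analysed here. Members without an adjusted p were left out of the tests.

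The genes named were Lhx4 and Bsx; the melatonin enzymes, Crx, Lhx9, Pax6 and Neurod1; per comparison, the 10 called genes with the highest and the 10 with the lowest log2 fold change among those with a mean of at least 50 and a gene symbol (names starting with LOC, RGD, AABR, ENSRNOG, AC or Rn left out); up to 4 members per list with the smallest adjusted p; up to 10 genes called in both comparisons; all genes with values per library; and, per comparison, the 3 genes with the smallest adjusted p. Values of 2 genes that this rule names are not reported here. Unchanged groups against shared siNT libraries were simulated in 100 draws. Alternatives were other thresholds, gene filters, centring, t references, list test settings, pseudocounts and leaving out each library of the 14 genes. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.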

Results

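RNA was sequenced from primary cultures of adult rat pinealocytes, the melatonin-producing cells of the pineal gland, after transfection with short interfering RNA (siRNA). The 9 libraries formed 3 groups of 3: a non-targeting siRNA (siNT), an siRNA against Lhx4 (siLhx4) and an siRNA against Bsx (siBsx), each at 40 nM. Lhx4 and Bsx encode homeodomain transcription factors, and the comparisons ask which transcripts of the adult gland depend on each of them. For both knockdowns, the authors' deposited tables listed log2 fold changes against siNT for 26854 genes, with adjusted p-values for the same genes in both. Values per library were used for 14 genes in the siNT and siLhx4 libraries. For these genes the size factors ranged from 0.761 in siLhx4 replicate 3 to 1.46 in siLhx4 replicate 1, and the lowest gene of each library had between 288 and 729 reads. The 6 highest entries of the siLhx4 table, all clone-based names without a gene symbol, held 41.0% of its summed mean normalized counts.

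Each siRNA lowered its target. Lhx4 was present at 18816 ± 432 normalized counts (SD, n = 3) in siNT and at 3535 ± 108 (SD, n = 3) in siLhx4, a level of 18.8% of siNT. The 3 siLhx4 libraries lay between 3420 and 3634 and the 3 siNT libraries between 18330 and 19156, and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. In the authors' deposited tables, Lhx4 fell by 2.41 ± 0.050 (log2, SE) with siLhx4 and Bsx fell by 2.27 ± 0.062 with siBsx (DESeq2 adjusted p = 5.25e-294), a change of -79.3%. Bsx also fell by 44.8% with siLhx4 (DESeq2 adjusted p = 3.23e-44 in the authors' deposited table). Lhx4 rose by 10.5% with siBsx (DESeq2 adjusted p = 0.0225 in the authors' deposited table). Values of Bsx per library, and any value per library of the siBsx group, were not analysed here. With 1 siRNA per target, effects of the siRNA sequence and of the lower target were not separated.

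In the 14 genes with values per library, 12 were lower and 2 higher in siLhx4 than in siNT. The groups of all 14 did not overlap, where chance gives 10% of genes. Each exact permutation p was 0.1, also after Benjamini-Hochberg adjustment over the 14 genes. The photoreceptor guanylate cyclase Gucy2d stood at 45.7% ± 2.25 of the siNT mean (SD, n = 3), and recoverin (Rcvrn), a calcium sensor of phototransduction, at 61.6% ± 11.8 (SD, n = 3). Aanat, which makes N-acetylserotonin at night, stood at 67.0% ± 2.70 (SD, n = 3), cone transducin Gnat2 at 67.4% ± 2.17 (SD, n = 3) and rhodopsin kinase Grk1 at 69.1% ± 2.06 (SD, n = 3). Pde6b, Cngb1, Tph1, Asmt, Slc24a1 and Calm3 lay between 71.0% and 77.8%. Guca1b, an activator of guanylate cyclase, stood higher, at 126% ± 3.42 (SD, n = 3). The authors chose these 14 genes on the same samples. Of the 14, 8 also belong to the rod and cone lists and 3 to the melatonin list described next, so those lists are not independent of that choice.

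**Figure D1:**
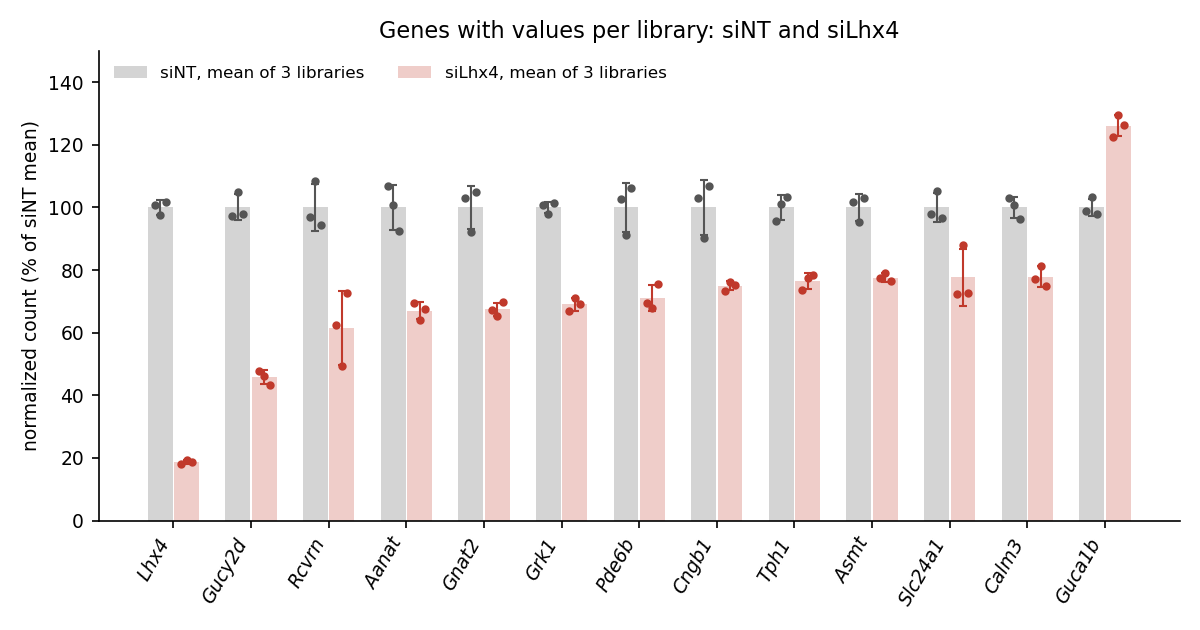
Normalized counts of 13 of the 14 genes with values per library, in percent of each gene's siNT mean (y axis), for siNT (grey) and siLhx4 (red); points are libraries, bars means of 3 and error bars SD. Lhx4 stands at 18.8% of siNT, 11 other genes stand between 45.7% and 77.8%, and Guca1b stands at 126%.

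With siLhx4, 2626 genes, 17.7% of those tested, passed an adjusted p of 0.05, 1200 higher and 1426 lower. The authors' deposited table showed that the matrix metalloproteinase gene Mmp3 fell by 2.17 ± 0.11 (log2, SE), a change of -77.8% (DESeq2 adjusted p = 1.98e-88). The nuclear import receptor Ipo4 fell by 1.94 ± 0.067 in the authors' deposited table (DESeq2 adjusted p = 2.63e-180), and the taurine transporter Slc6a6 fell by 1.13 ± 0.044. After Lhx4 itself, Ipo4 and Slc6a6 had the smallest p-values. Neurotrophin 3 (Ntf3), the neurturin co-receptor Gfra2, the cadherin Cdh9, neuroglobin (Ngb), 4932431P20Rik, the surface glycoprotein Cd200 and Arpp21 had log2 fold changes from -1.94 to -1.59 in the authors' deposited table. Among genes with a symbol and a mean of at least 50 normalized counts, the largest rises there were those of the transcription factor Sox18 (3.33-fold), the calcium-binding protein Cabp7 (3.28-fold), the proteolipid Mal (3.19-fold) and the α2A-adrenergic receptor Adra2a (2.89-fold). Scube1, the protocadherin Pcdh19, Klhl5, the endothelial diaphragm protein Plvap, Rd3l and the adhesion protein Kirrel2 rose by 2.64-fold to 2.86-fold in the authors' deposited table. Most changes were small, with a median size of 0.36 on the log2 scale (1.28-fold) among the called genes in the authors' deposited table, and 65 higher and 57 lower genes changed 2-fold or more.

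All 4 enzymes from tryptophan to melatonin fell with siLhx4. In the authors' deposited table, Aanat fell by 33.0%, the aromatic amino acid decarboxylase Ddc fell by 24.4%, tryptophan hydroxylase (Tph1) fell by 23.6% and the last enzyme, Asmt, fell by 22.4%, with DESeq2 adjusted p-values from 1.33e-21 to 8.02e-12. The other 9 of 13 members of the melatonin list, which make cofactors or carry amino acids, did not pass, and the list as a whole was lower (limma's cameraPR test, adjusted p = 5.13e-05). Of 23 rod phototransduction genes, 13 fell and 2 rose (cameraPR adjusted p = 1.24e-06). By the authors' deposited table, Gucy2d fell by 1.12 ± 0.10 on the log2 scale, the retinoid carrier Rbp3 by 0.51 ± 0.052 and Grk1 by 0.53 ± 0.060. Guca1b rose by 0.33 ± 0.043 there. Of 9 cone genes, 4 fell: Pde6c (log2 fold change -0.51), Gnat2 (-0.57), the transducin β3 subunit Gnb3 (-0.23) and Gngt2 (-0.22) in the authors' deposited table (cameraPR adjusted p = 0.00372). Of 23 genes of ribbon synapses and exocytosis, 12 fell and 3 rose (cameraPR adjusted p = 9.74e-09). The calcium sensor of vesicle release Syt1 had a log2 fold change of -0.93, the complexin Cplx4 -0.82, the priming factor Unc13b -0.73 and the granule protein Scg2 -0.79 in the authors' deposited table. The libraries with these lower pineal lists also had higher fibroblast and astrocyte markers, with list medians of 0.40 and 0.10 on the log2 scale.

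Among 17 transcription factors of the pineal and retina, 7 fell with siLhx4 and 1 rose (cameraPR adjusted p = 2.79e-16). Besides Lhx4 and Bsx, the islet factor Isl2 fell by 1.25 ± 0.075 and the microphthalmia factor Mitf by 1.21 ± 0.083 on the log2 scale in the authors' deposited table. Without Lhx4 and Bsx in the list, 5 of 15 fell and 1 rose (cameraPR adjusted p = 0.00513). The median log2 fold change of these 15 was -0.005, and other forms of the test were run only on the full list. Pax6 was the member that rose, 1.44-fold (DESeq2 adjusted p = 4.9e-05 in the authors' deposited table). The photoreceptor factor Crx (-0.11 ± 0.044), Neurod1 (-0.09 ± 0.053) and Lhx9 (0.53 ± 0.28) did not pass in the authors' deposited table (log2 fold change and SE; DESeq2 adjusted p of 0.0589, 0.255 and 0.195). Of 19 night-induced genes under cAMP control, 6 fell and 4 rose (cameraPR adjusted p = 0.0113). The phosphodiesterase Pde4b had a log2 fold change of -0.86, the dopamine receptor Drd4 -0.83 and Irs2 -0.27 in the authors' deposited table. Of 18 tested genes of adrenergic signalling, 4 fell and 4 rose. The cameraPR test put this list lower (adjusted p = 0.0111) and its mean was -0.12, while its median was 0.02. Among its members, the protein kinase A subunit Prkar2b had a log2 fold change of -1.34, Pde4b -0.86, the stimulatory G protein Gnas -0.60 and Prkar2a -0.64 in the authors' deposited table. Without Gnas, Prkar2b and Pde4b, a subset chosen after the values were seen, the call was lost (cameraPR adjusted p = 0.398). Of 21 clock genes, 5 rose and 4 fell (cameraPR adjusted p = 0.164), with Bhlhe40 at 0.46, Clock at 0.32 and Npas2 at -0.46 on the log2 scale in the authors' deposited table.

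Sterol synthesis genes fell with siLhx4, and several markers of other cell types rose. Of 18 cholesterol synthesis genes, 10 fell, among them Insig1 (log2 fold change -0.62), Idi1 (-0.54) and Lss (-0.41) in the authors' deposited table (cameraPR adjusted p = 3.59e-06). Of 14 fibroblast markers, 5 rose, with the collagens Col6a2 at 0.97 and Col6a1 at 0.79 and the receptor Pdgfra at 0.66 on the log2 scale in the authors' deposited table (cameraPR adjusted p = 0.00077). Of 10 astrocyte markers, 4 rose: Vim by 0.50, Apoe by 0.37, Glul by 0.35 and Sox9 by 0.36 on the log2 scale in the authors' deposited table (cameraPR adjusted p = 0.045). The endothelial, mural and Schwann lists did not pass (cameraPR adjusted p of 0.112, 0.112 and 0.164), with Plvap, Myh11 and, of the Schwann list, Mal and Cnp higher. None of 10 microglial markers passed DESeq2's test, and 0 had an unadjusted p under 0.05. Of 19 cell cycle genes, 3 rose: the proliferation marker Mki67 by 0.57, Tyms by 0.64 and Top2a by 0.51 on the log2 scale in the authors' deposited table (cameraPR adjusted p = 0.0128). Of 21 interferon response genes, Irf1 and Oasl rose, by 0.68 and 0.33 on the log2 scale in the authors' deposited table, and the list median was 0.50 (cameraPR adjusted p = 0.0296). The other 19 did not pass, 4 of them below 0, and many had wide standard errors at high counts, such as Irf7 at 0.51 ± 0.38 and Irf9 at 0.43 ± 0.40 on the log2 scale in the authors' deposited table (SE). Whether single libraries stood apart in these genes could not be tested without their values per library. Of 21 stress and apoptosis genes, 6 fell and 2 rose, with Gdf15 at -0.39 and Sesn2 at -0.36 on the log2 scale in the authors' deposited table (cameraPR adjusted p = 0.0483). Adjusted over the list alone, the siLhx4 counts were 2 higher and 14 lower rod genes, 1 higher and 5 lower cone genes, 2 higher and 8 lower transcription factors, 1 higher and 12 lower sterol genes, 6 higher fibroblast markers and 3 higher endothelial markers, and those of the other 12 lists were equal to the counts over all genes. The calls of the rod, synapse, cholesterol and fibroblast lists held under every alternative form of the list test, whereas each of the other siLhx4 list calls was lost under at least 1. With a t reference of 4 degrees of freedom in place of DESeq2's normal reference, 1 gene passed, and with 6 degrees of freedom 699 did. Here and below, these degrees of freedom were set from the number of libraries and not from DESeq2's fit. At 4, even Ipo4 (log2 fold change -1.94 ± 0.067, SE, in the authors' deposited table) no longer passed. These counts therefore do not show how many of the calls are false.

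With siBsx, 2558 genes, 17.2% of those tested, passed an adjusted p of 0.05, 1129 higher and 1429 lower. The chemokine-like Fam19a3 of the authors' deposited table fell by 2.38 ± 0.26 (log2, SE), the co-repressor Tle6 by 1.94 ± 0.16 and the immunoglobulin-domain protein Igsf9 by 1.89 ± 0.16. The T-type calcium channel Cacna1g fell by 67.5% and the calcium-binding protein Cabp1 fell by 67.7% (DESeq2 adjusted p of 3.02e-65 and 1.24e-130 in the authors' deposited table). Gnb3, the β subunit of cone transducin, fell by 58.1% (DESeq2 adjusted p = 2e-146 in the authors' deposited table) and, after Bsx, had the smallest p-value. The tryptase Tpsg1, Bcap29, the zinc-finger factor Bcl11b and the nitric oxide synthase Nos1 had log2 fold changes from -1.91 to -1.67 in the authors' deposited table. Among genes with a symbol and a mean of at least 50 normalized counts, protocadherins were among the 10 largest rises in the authors' deposited table, with Pcdh19 at 3.67-fold, Pcdh8 at 3.24-fold and Pcdh17 at 2.96-fold. Gpsm2, the adaptor Apbb1, Magel2, the cardiac actin Actc1, the gap junction protein Gjd2, Vat1l and Plekhg1 rose by 2.90-fold to 3.35-fold in the authors' deposited table. Among the called genes of the authors' deposited table, 70 higher and 84 lower changed 2-fold or more.

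The melatonin enzymes moved little with siBsx. In the authors' deposited table, Aanat fell by 16.4% and Tph1 fell by 8.86%, Asmt rose by 10.5% and Ddc was at 7.17% above siNT without passing (DESeq2 adjusted p of 0.000115, 0.00826, 0.0239 and 0.17). Over the 13 members, 4 fell and 3 rose, the median was 0.04 and the mean -0.03 on the log2 scale, and the test put the list lower without passing (cameraPR adjusted p = 0.695). Of 9 cone genes, 4 fell and 1 rose (cameraPR adjusted p = 2.49e-07), with Gnb3 at -1.25, Gngt2 at -0.67, Gnat2 at -0.47 and Pde6c at -0.31 on the log2 scale in the authors' deposited table. The rod list split: 11 of 23 fell and 5 rose (cameraPR adjusted p = 0.314). By the authors' deposited table, Cngb1 fell by 0.78 ± 0.066 and Grk1 by 0.69 ± 0.061 on the log2 scale, while Guca1b rose by 0.83 ± 0.043 and the rod arrestin Sag by 0.83 ± 0.044. Of 23 synapse genes, 8 fell and 5 rose (cameraPR adjusted p = 0.122), with the complexin Cplx3 at -0.71, the calcium channels Cacna1f at -0.84 and Cacna1c at -0.66 and the vesicular glutamate transporter Slc17a7 at -0.33 in the authors' deposited table. Of 18 adrenergic signalling genes, 7 rose and 1 fell (cameraPR adjusted p = 3.59e-06). The phosphodiesterase Pde4d rose by 0.80 ± 0.069, the α1B receptor Adra1b by 0.58 ± 0.059, Ywhaz by 0.44 ± 0.048 and Prkar2b by 0.59 ± 0.077 in the authors' deposited table. Of 19 night-induced genes, 6 rose and 7 fell (cameraPR adjusted p = 0.642), with the copper transporter Atp7b at 1.46, Id1 at -0.43 and Nr4a1 at -0.34 in the authors' deposited table. The libraries with these changes also had lower astrocyte and mural markers, with list medians of -0.33 and -0.65 on the log2 scale.

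Of 17 transcription factors, 6 rose and 4 fell with siBsx; the median was 0.14, the test put the list lower without passing (cameraPR adjusted p = 0.262), and without Lhx4 and Bsx it pointed up (cameraPR adjusted p = 0.12). Isl2 rose by 0.75 ± 0.071, Neurod1 by 0.28 ± 0.053 and Crx fell by 0.19 ± 0.044 on the log2 scale in the authors' deposited table. Pax6 (-0.02 ± 0.12) and Lhx9 (0.19 ± 0.28) did not pass there. Of 21 clock genes, 5 rose and 4 fell (cameraPR adjusted p = 0.394), with Bhlhe41 at 0.78 and Ciart at 0.62 in the authors' deposited table. Of 18 cholesterol synthesis genes, 14 fell, among them the synthase Hmgcs1 (log2 fold change -0.65), Insig1 (-0.50) and Msmo1 (-0.60) in the authors' deposited table (cameraPR adjusted p = 6.98e-11). Of 10 astrocyte markers, 4 fell: the connexin Gja1 by 1.31 ± 0.11, Glul by 0.47 ± 0.087, Apoe by 0.31 ± 0.088 and Aldoc by 0.34 ± 0.098 in the authors' deposited table (cameraPR adjusted p = 0.00139). Of 7 mural markers, Myh11 fell by 1.07 ± 0.074 and Pdgfrb by 0.65 ± 0.16 in the authors' deposited table (cameraPR adjusted p = 0.00329). The smooth muscle myosin Myh11 had a mean of 4576 normalized counts in the authors' deposited table, against 394 for Pdgfrb. Of 14 fibroblast markers, 4 fell without the list passing (cameraPR adjusted p = 0.0851), among them Pdgfra by 0.56 ± 0.15 and Col6a1 by 0.51 ± 0.17 in the authors' deposited table. The microglial, endothelial, Schwann, interferon, stress and cell cycle lists did not pass (cameraPR adjusted p of 0.313, 0.857, 0.338, 0.29, 0.392 and 0.658). Of these, the microglial Cd68 and the Schwann list's Mal rose, 3 of 21 interferon genes fell and 1 rose, and 4 of 21 stress genes rose and 2 fell. Rsad2 fell by 1.05 ± 0.18 and the stress factor Xbp1 rose by 0.58 ± 0.074 in the authors' deposited table. None of the 10 endothelial and 19 cell cycle genes passed DESeq2's test, and 1 and 0 of them had an unadjusted p under 0.05. Adjusted over the list alone, the siBsx counts were 6 higher and 12 lower rod genes, 6 and 9 synapse genes, 8 and 1 adrenergic genes, 7 and 8 night-induced genes, 6 and 5 clock genes, 15 lower sterol genes and 3 lower mural markers, and those of the other 11 lists were equal to the counts over all genes. The calls of the adrenergic, cholesterol and astrocyte lists held under every alternative form of the list test, whereas those of the cone and mural lists were lost under at least 1. With a t reference of 4 degrees of freedom 36 genes passed, and with 6 degrees of freedom 795 did.

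**Figure D2:**
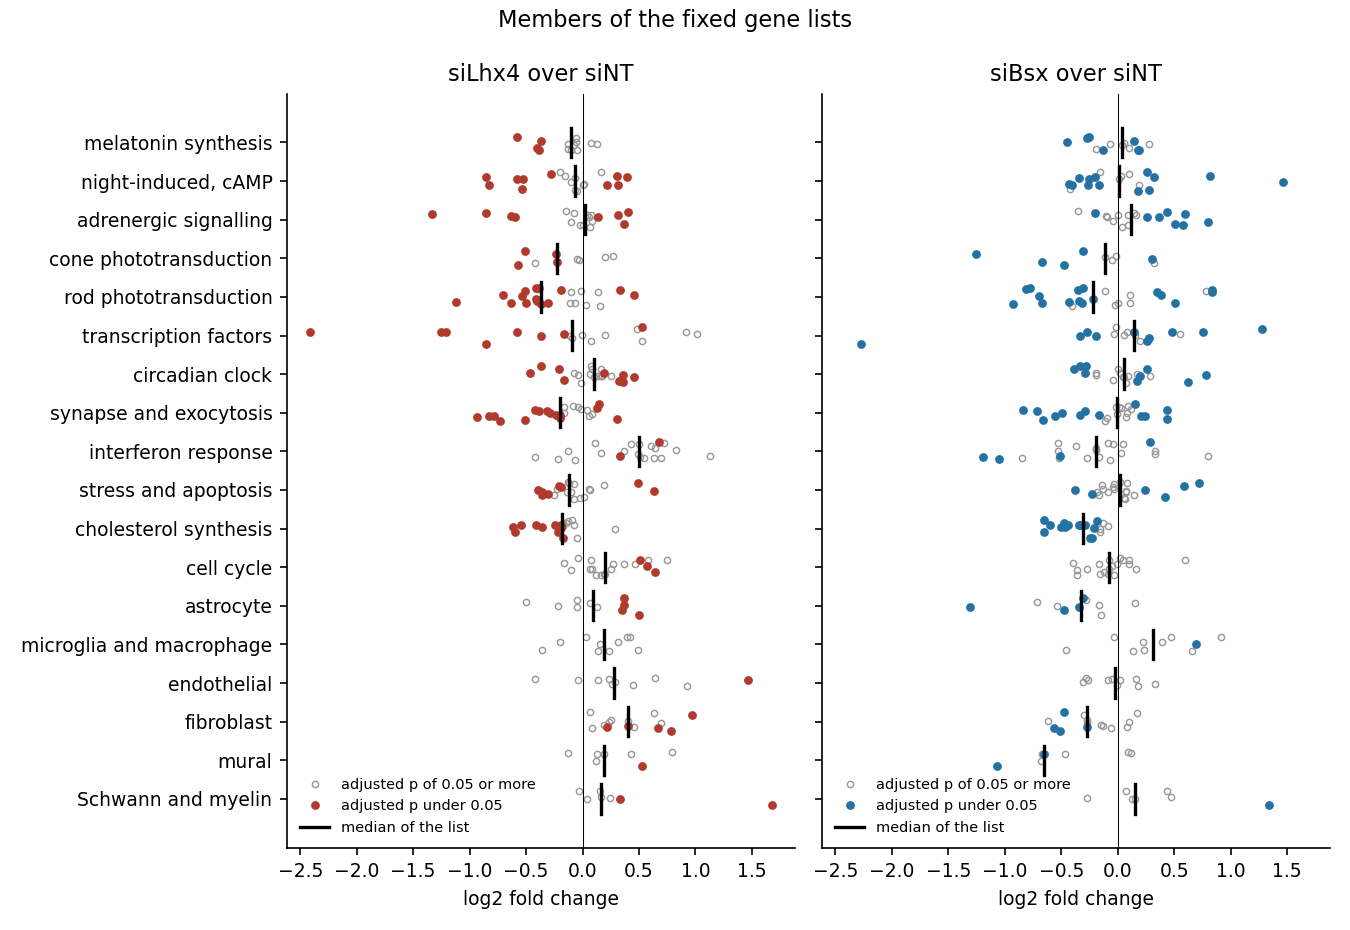
Log2 fold changes over siNT (x axes) of the tested members of the 18 fixed gene lists (y axis) with siLhx4 (left) and siBsx (right); filled points passed an adjusted p of 0.05, open points did not, and black ticks mark list medians. The cholesterol list has a median of -0.18 with siLhx4 and -0.31 with siBsx, and the mural list 0.19 and -0.65.

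The knockdowns shared part of their changes. Of the genes called in both comparisons, 389 were higher and 468 lower in both, against 91.1 and 137 for independent lists of the same sizes. Another 227 changed in opposite directions, 114 of them higher with siLhx4 and lower with siBsx and 113 the reverse, against 115 and 108 for independent lists. Among the shared genes with the smallest p-values, the phosphatase Ppef2 fell by 46.5% with siLhx4 and fell by 57.8% with siBsx in the authors' deposited tables. The collagen Col8a1 changed by -38.3% and -32.1% and Reep2 by -39.7% and -45.4% in the authors' deposited tables. The chemokine Cxcl14 rose 2.42-fold and 2.73-fold, Rasgef1b 1.76-fold and 1.91-fold, the chloride transporter Slc12a2 1.81-fold and 1.74-fold, and the actin-severing protein Cfl2 1.77-fold and 1.51-fold in the authors' deposited tables. Efcab14 and the branched-chain aminotransferase Bcat1 went opposite ways: Efcab14 fell by 34.5% with siLhx4 and rose 1.88-fold with siBsx, and Bcat1 rose 1.49-fold with siLhx4 and fell by 35.8% with siBsx in the authors' deposited tables. Across the tested genes, which are not independent replicates, Pearson's r between the comparisons was 0.344 and Spearman's rho 0.314, and 61.2% of genes had the same sign. Simulated unchanged groups against the same siNT libraries gave a mean r of 0.50, a rho of 0.454 and 66.7%, and 0 genes called in both. That r and the 0 calls follow from the simulation's design, with no true change and known standard errors. They do not measure how far shared siNT error adds to the overlap of called genes. The covariance was 0.0328 observed and 0.0219 simulated, a difference of 0.0109. Part of the overlap beyond that of independent lists may come from the siNT libraries that both comparisons used, since 3 libraries were too few to split between them. At an adjusted p of 0.01 in both comparisons, 548 genes were called in the same direction, against 857 at 0.05.

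**Figure D3:**
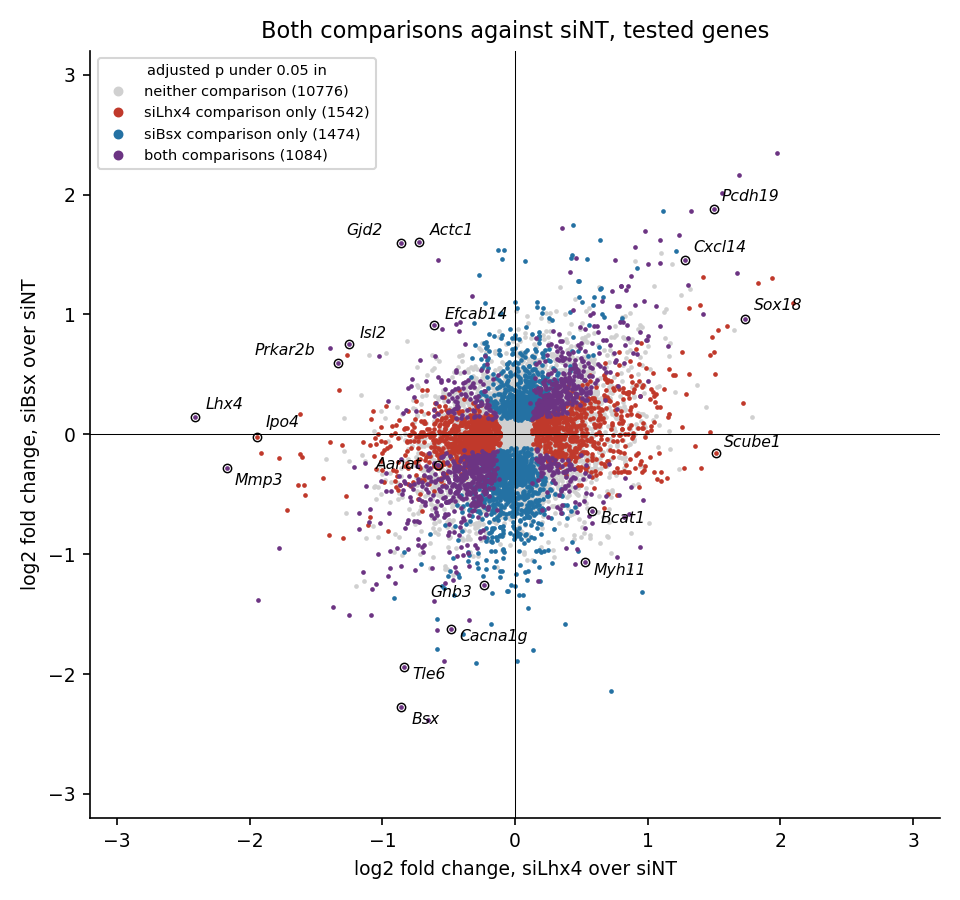
Log2 fold change with siLhx4 (x axis) against that with siBsx (y axis), both over siNT, for the tested genes; colour shows in which comparison a gene passed an adjusted p of 0.05, and named genes are circled. Of the 1084 genes called in both, 857 lie in the lower left and upper right quadrants and 227 in the other two.

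A direct test of siBsx against siLhx4, rebuilt from both deposited tables, called 3380 genes, 1613 higher and 1767 lower in siBsx. Of the 857 genes called in the same direction with both, 236 differed. Of 1542 genes called with siLhx4 alone, 1020 differed between the knockdowns, and of 1474 called with siBsx alone, 970 did. The 4 melatonin enzymes differed as well, with Asmt 0.51 ± 0.049, Ddc 0.50 ± 0.050, Aanat 0.32 ± 0.058 and Tph1 0.25 ± 0.041 higher in siBsx than in siLhx4 on the log2 scale (rebuilt Wald test, adjusted p from 5.3e-23 to 4.9e-07). The melatonin list as a whole was higher in siBsx (cameraPR adjusted p = 0.00257), as were the transcription factor (3.27e-08), synapse (0.00128), rod (0.00257), night-induced (0.00905), stress (0.0108) and adrenergic (6.5e-10) lists. The fibroblast (9.33e-06), astrocyte (5.21e-06), mural (5.67e-05), interferon (0.0038) and cell cycle (0.0108) lists were lower in siBsx. The cholesterol list (0.0833), the cone list (0.0517) and the clock, endothelial, microglial and Schwann lists (from 0.116 to 0.703) did not pass this test. Without Lhx4 and Bsx, whose own differences are part of the list, the transcription factor list was also higher in siBsx, with 5 of 15 higher and 1 lower (cameraPR adjusted p = 0.000168); other forms of the test were run only on the full list, from 2.1e-08 to 0.281. The adrenergic, fibroblast, astrocyte, mural and interferon calls held under every alternative form of the list test, whereas those of the melatonin, transcription factor, synapse, rod, night-induced, stress and cell cycle lists were each lost under at least 1, and the endothelial list passed under 2. Of the interferon list 6 of 21 members passed the direct test, and the wide standard errors of the others apply here too. With a t reference of 6 degrees of freedom the direct test called 1307 genes.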

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

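The tests of the difference between the knockdowns and every test of an explanation here were chosen after the results were seen. Differences are siBsx minus siLhx4 on the log2 scale, with the SE of the rebuilt Wald test.

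Several named genes moved in opposite directions with the knockdowns, each called in both. Besides the target Lhx4 (difference 2.56), the gap junction gene Gjd2 differed by 2.46 ± 0.076, the cardiac actin Actc1 by 2.33 ± 0.18, the transcription factor Isl2 by 2.01 ± 0.074, the protein kinase A subunit Prkar2b by 1.93 ± 0.078, Efcab14 by 1.52 ± 0.043 and the complexin Cplx4 by 1.03 ± 0.065, all lower with siLhx4 and higher with siBsx. The myosin Myh11 differed by -1.60 ± 0.074, the collagen Col6a1 by -1.30 ± 0.17, the receptor Pdgfra by -1.23 ± 0.15 and the aminotransferase Bcat1 by -1.22 ± 0.049, all higher with siLhx4 and lower with siBsx. The adrenergic signalling list was higher with siBsx than with siLhx4 (cameraPR adjusted p of the difference = 6.5e-10); with siLhx4 alone, 4 members were higher and 4 lower, with a median of 0.02, and the direction of its test turned on ranks. The astrocyte list was lower with siBsx than with siLhx4 (cameraPR adjusted p of the difference = 5.21e-06); with siLhx4 alone, 4 of 10 members were higher, with a median of 0.10, and the list's call was lost under 3 of 4 other settings.

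Markers of other cell types were higher with siLhx4 for fibroblasts and, less firmly, astrocytes, and lower with siBsx for astrocytes and mural cells. Those tested were 14 of 15 fibroblast, 10 of 14 astrocyte and 7 of 12 mural markers. The astrocyte markers Gfap and Aqp4 and the mural markers Rgs5 and Acta2 were among those without an adjusted p. The tested members may therefore not track these cell types. A different share of non-pinealocyte cells as a whole would move the 6 marker lists alike, if pinealocytes expressed none of the markers. With siBsx the lists moved apart (permutation p = 1e-05, the smallest that 100000 permutations can give). Under that condition, this argues against such a share as the sole cause there and leaves open a change in single cell types. The permutation treats marker genes as independent, so its p does not measure the spread between libraries. With siLhx4 the p was 0.207, which does not show that the lists moved alike, so a different share of these cells and regulation of the markers within cells cannot be told apart. Among the most abundant markers were Myh11, Vim and Apoe, at mean normalized counts of 7566, 5382 and 3050 in the authors' deposited siLhx4 table; of the 58 tested markers 0 were in another list, and how many pinealocytes express was not analysed here.

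Of 128 genes with a mean of at least 50 that changed 2-fold or more with siBsx, the targets left out, 100 had the same direction with siLhx4, 57 of them called, and 8 were called in the opposite direction. Their slope of siLhx4 on siBsx log2 fold changes was 0.336 (95% bootstrap interval over genes 0.269 to 0.405). The sampling error of the shared siNT libraries alone, taken from the deposited standard errors, gave a slope of 0.0136, which argues against that error as the whole cause. Intervals over genes, here and for the reverse slope, leave out the spread between libraries, since all genes were measured in the same ones. Because Bsx itself was lower with siLhx4, at a ratio of log2 changes of 0.377, a candidate explanation is that part of the siLhx4 changes follow from less Bsx. The reverse slope, over 94 genes changed 2-fold or more with siLhx4, was 0.324 (0.228 to 0.423) although Lhx4 was not lower with siBsx, so lower Bsx and a response common to both siRNAs cannot be told apart. Effects of the non-targeting siRNA on the shared siNT libraries were not tested.

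The 4 melatonin synthesis enzymes were lower with siLhx4. A lower share of pinealocytes would lower Crx and Neurod1 as far as the enzymes, if their level per pinealocyte stayed the same. The enzymes fell further, by a mean log2 difference of -0.331 ± 0.043 (SE). Under that condition, this argues against that share as the whole cause. The small changes of these 2 reference genes were known when they were chosen. Other pineal genes fell as far as the enzymes, such as Rbp3 (-0.51) and Gnat2 (-0.57) in the authors' deposited table, while Guca1b rose (0.33). Other references would thus have given other differences. The enzymes had a mean log2 fold change of -0.43, so against Rbp3 or Gnat2 they would not have fallen further. A factor common to all genes of a library leaves the difference of -0.331 as it is. If the true levels of Crx and Neurod1 did not change, the same value argues against a shift of the normalization as the whole cause. Since these 2 references were chosen with their small changes known, the value cannot show this without that condition. Lower Bsx as the whole cause is argued against by siBsx, where Bsx fell further but the enzymes were on average 0.397 ± 0.025 (log2, SE) higher than with siLhx4. The SEs of both mean differences treat the genes as independent although they were measured in the same libraries, so their size is uncertain. A dependence of the enzymes on Lhx4 may explain the pattern as a hypothesis, and an effect of the siRNA sequence apart from Lhx4 stays untested.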

How the results depend on the processing

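The t reference with 6 degrees of freedom, the alternatives of the direct test and of its lists, and the lists without single members were chosen after the data were seen. Counts of called genes stayed within 1.5 times at adjusted p of 0.01 and 0.1, under 3 other sets of genes for the adjustment and after centring, from 1817 to 3344 for siLhx4 and from 1800 to 3202 for siBsx. A minimum 2-fold change left 122 and 154 genes by its construction. A t reference with 4 degrees of freedom, on the same standard errors, left 1 and 36, and one with 6 left 699 and 795 (and 1307 for the direct test, 3439 with the other table's dispersion). Both degrees of freedom were set from the number of libraries and not from DESeq2's fit, so these losses do not measure false calls. Genes called in the same direction in both comparisons numbered 548 at 0.01 and from 728 to 1125 under the other settings. There were 182 results of named genes, some of them without a call, such as Crx, Neurod1 and Lhx9 with siLhx4. Of their calls, 160 were lost at 4 degrees of freedom and 2, Cnp and Gngt2 with siLhx4, with adjustment over all listed p-values. At 6 degrees of freedom, with the named genes of the direct test included, 67 calls were lost and 256 results stayed the same.

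List tests with siLhx4 depended on the setting in these cases (cameraPR adjusted p, with the range over the 4 planned settings). On ranks, the night-induced list gave 0.188, the adrenergic list 0.928 with its direction reversed, the cone list 0.078, the transcription factors 0.283, the astrocyte list 0.124 and the endothelial list 0.0394. With a correlation of 0.05, the night-induced list gave 0.0635, adrenergic 0.061, interferon 0.116, stress 0.161, cell cycle 0.0673 and astrocyte 0.103. With a mean of at least 50, stress gave 0.0598. With the log2 fold change in place of the statistic, melatonin gave 0.104, night-induced 0.0758, adrenergic 0.154, cone 0.15, stress 0.383, astrocyte 0.413, endothelial 0.000756, mural 0.0327 and Schwann 0.00833. Ranges were 9.86e-05 to 0.104 for melatonin, 0.0154 to 0.188 for night-induced, 0.0152 to 0.928 for adrenergic, 0.00538 to 0.15 for cone, 6.94e-19 to 0.283 for transcription factors, 1.96e-06 to 0.116 for interferon, 0.0328 to 0.383 for stress, 0.00313 to 0.0673 for cell cycle, 0.0332 to 0.413 for astrocyte, 0.000756 to 0.188 for endothelial, 0.0327 to 0.174 for mural and 0.00833 to 0.241 for Schwann.

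With siBsx, ranks gave 0.124 for cone, 0.0153 for fibroblast and 0.0519 for mural, and the log2 fold change gave 0.0531 for cone, 0.0113 for interferon, 0.00313 for microglia, 0.028 for fibroblast and 0.0101 for Schwann. Ranges were 7.04e-07 to 0.124 for cone, 0.000756 to 0.0519 for mural, 0.0153 to 0.174 for fibroblast, 0.0113 to 0.426 for interferon, 0.00313 to 0.458 for microglia and 0.0101 to 0.426 for Schwann. For the difference of siBsx and siLhx4, ranks gave 0.19 for night-induced, 0.184 for rod, 0.281 for transcription factors, 0.0671 for synapse and 0.0402 for endothelial, and a correlation of 0.05 gave 0.056 for stress and 0.0545 for cell cycle. The log2 fold change gave 0.175 for melatonin, 0.0518 for rod, 0.0847 for synapse, 0.131 for stress and 0.00159 for endothelial. Ranges were 0.00345 to 0.175 for melatonin, 0.012 to 0.19 for night-induced, 0.00345 to 0.184 for rod, 2.1e-08 to 0.281 for transcription factors, 0.00198 to 0.0847 for synapse, 0.0106 to 0.131 for stress, 0.00166 to 0.0545 for cell cycle and 0.00159 to 0.18 for endothelial. The cause was not tested for any of these lists.

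Because the groups of all 14 genes with values per library did not overlap, other pseudocounts, linear values and leaving out a library could not bring them to overlap and were no test of their separation. The log2 difference of Lhx4 ranged from -2.43 to -2.39 without each library. Over these 14 genes, samples of the same number deviated from their group means with correlations of 0.193, -0.123 and -0.031. Samples of different numbers had correlations from -0.315 to 0.161. This gave no sign of pairing by number, but 14 genes are too few to exclude it. With the number as a block, the same lack of overlap fixed 1 direction in every pair for 14 of 14 genes, at the smallest exact p that 3 pairs allow, 0.25. For all-gene counts, the replicate block, leaving out libraries, pseudocounts, no filter, DESeq2 size factors, TMM rescaling and fits of only 2 groups were not run, since they need values per library, and so were other splits of the samples; a mean of at least 10 removed none of the 14 genes.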

Other observations

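The test of gene families, defined by a shared symbol root among 145 roots with at least 10 tested members, was chosen after the data were seen. With siBsx, voltage-gated calcium channel genes (Cacna) were lower as a family, with 8 of 13 members lower, 0 higher and a median log2 fold change of -0.37 (cameraPR adjusted p = 1.59e-13). The T-type channel Cacna1h, chosen after its values were seen, fell by 1.34 ± 0.055 and Cacna1g by 1.62 ± 0.093 on the log2 scale in the authors' deposited table. Protocadherins of the root Pcdh, which mediate adhesion between neurons, were higher with siBsx, with 6 of 10 higher, Pcdh1 lower and a median of 0.97 (cameraPR adjusted p = 0.000209). With siLhx4, 7 of these 10 were higher and 1 lower without the family passing (cameraPR adjusted p = 0.0567). Another 13 protocadherins, of the root Pcdhb, did not pass as a family (cameraPR adjusted p of 0.987 with siBsx and 0.895 with siLhx4); DESeq2 called 0 of them with either siRNA, and 0 had an unadjusted p under 0.05. Collagens (Col) were lower with siBsx, with 11 of 35 lower, 0 higher and a median of -0.24 (cameraPR adjusted p = 0.0122); 6 of them also belong to the fibroblast list. Sox transcription factors were higher with siLhx4, with 5 of 10 higher, 0 lower and a median of 0.35 (cameraPR adjusted p = 0.0362), among them Sox18 and the astrocyte marker Sox9.

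The median of the 18 cholesterol synthesis genes stood at percentile 0.07 (0.07% of lists) with siLhx4 and 0 with siBsx among 10000 random lists matched on mean level. Random lists leave out correlation between the genes of a list, so these percentiles do not give an error rate. Of the 18 genes, 8 differed between the knockdowns, adjusted over the list alone. Ipo4, which fell with siLhx4, had a log2 fold change of -0.03 with siBsx in the authors' deposited table, a difference of 1.92 ± 0.068. The deposited standard errors of the mean of the 14 genes were in percent of the mean for 4 genes and in normalized counts for 10. Entries with clone-based or locus names held 57.0% of the summed mean normalized counts of the siLhx4 table.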
